A study of Psychotria gabriellae and Psychotria semperflorens with 6 samples.

How the data were processed

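Leaf messenger RNA was sequenced from 6 wild plants, 3 of Psychotria gabriellae and 3 of Psychotria semperflorens, shrubs of the coffee family from New Caledonia. The labels call the first species a nickel hyperaccumulator, a plant that concentrates the metal in its leaves, and the second a non-accumulator. Each library came from 1 plant, so the replicates are separate individuals. Per the labels' protocols, leaves were frozen in liquid nitrogen in the field, total RNA was extracted with a CTAB method and treated with DNase, and polyA libraries were made with a kit that keeps strand.

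Per the series' design text, reads of 1 plant of each species were assembled de novo, and the P. gabriellae assembly served as the common reference for both species. The design text does not say which plant was assembled. The values deposited by the authors are raw read counts per contig, as whole numbers with a different total in each library, for the same 60899 contigs in all 6 libraries. The aligner, the counting tool, its use of strand and any filter are not given in the sources used here. A contig is an assembled sequence and not a gene: alleles, isoforms, close paralogs and fragments of 1 gene can occupy several contigs, and reads can be split between them. Reads of P. semperflorens were counted on sequences of another species, which can lower their counts where the species differ in sequence. The files do not pair contigs with gene names or sequences and no reference was used here, so contigs are given by their identifiers and no position or annotation can be stated. For this reason 18 gene lists fixed before the data were examined, covering metal transport, metal chelation and leaf biology, were not tested.

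Counts were analysed in R 4.3.3 with edgeR 4.0.16. Contigs were kept with filterByExpr by species, which left 53478 contigs holding at least 99.6% of the reads of each library. Libraries were scaled with TMM factors, and CPM values, counts scaled to a common library total, were computed from the scaled library sizes. The CPM values for sequencing depth, for detection in 1 species and for contigs set apart in 1 or 2 libraries use unscaled totals instead. The species were compared with edgeR's quasi-likelihood test with species as the sole term, and p-values were adjusted by the Benjamini-Hochberg method. A contig was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Sites were compared in a model with species and site. Detection in 1 species was counted, without a test, as at least 10 reads in each library of that species and 0 in each library of the other. The spread between plants was given as edgeR's common biological coefficient of variation, fitted for each species alone.

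The contigs named in the comparison of species followed a rule fixed before the data were examined. They are the 2 with the largest and the 2 with the smallest log2 fold change among called contigs whose groups did not overlap and whose mean CPM over the 6 libraries was at least 10. Alternatives covered other normalizations, filters and thresholds, DESeq2 1.42.0, the edgeR likelihood ratio test, limma-voom (limma 3.58.1), blocks for replicate number and for collection day, site as a covariate, and leaving out each library.

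The labels give a collection day for each plant, and on each of 3 days 1 plant of each species was taken. Collection day therefore pairs the libraries. The replicate numbers follow the days only for the plants numbered 2, both taken on March 10. After removing each species' mean, log2 CPM of the plants that shared a day correlated across contigs at 0.16 for October 30, 0.17 for March 10 and -0.06 for November 4. The comparison fixed beforehand has no block, and the value with collection day as a block stands beside it. Every pair of libraries differed far beyond sampling noise (chi-square per degree of freedom 124 or more), so no pair of libraries was counted as 1 sample.

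The tests were tested on simulated counts with the means, library sizes and dispersions of the species comparison, 52186 contigs after filtering, of which 100 were changed 4-fold and 100 were changed 16-fold. The changed contigs were drawn only from those above a minimum mean read count, so the recovered numbers do not cover scarcer contigs. The quasi-likelihood test recovered 64 of the 16-fold and 1 of the 4-fold changes with 4 false calls. With the collection-day block it recovered 25 and 0, with 2 false calls. Limma-voom recovered 66 and 1 with 3 false calls. DESeq2 recovered 97 and 33 with 206 false calls, and the likelihood ratio test 92 and 26 with 121 false calls. With 3 plants per species and this spread between plants, the quasi-likelihood test and limma-voom thus rarely detected a 4-fold difference.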

Results

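Leaf transcriptomes of 2 Psychotria species growing wild in rain forest on serpentine soil were compared. Psychotria gabriellae hyperaccumulates nickel and P. semperflorens does not. Each species was represented by 3 plants. On October 30 and on November 4, 1 plant of each species was collected at Monts Koghi, and on March 10 of the following year 1 plant of each species was collected at Rivière Blanche. P. gabriellae plants 1, 3 and 2 and P. semperflorens plants 3, 1 and 2 were taken on these days, in that order. Read counts on the contigs of the P. gabriellae transcriptome summed to 55997877, 62064930 and 29905486 for P. gabriellae plants 1, 2 and 3. The totals were 45930829, 58201917 and 53662040 for P. semperflorens plants 1, 2 and 3. At these depths 10 reads corresponded to between 0.161 and 0.334 CPM on unscaled totals.

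Nearly all contigs held reads in both species. Of 60899 contigs, 60897 had at least 1 read in P. gabriellae plant 1, and between 57474 and 58837 had one in each of the other 5 libraries. The 10 most abundant contigs took 10.7% of the reads in P. gabriellae plant 1 and 9.12% in P. semperflorens plant 3, against 6.55% to 7.25% in the other 4 libraries. Among the 100 most abundant contigs of each library, 36 were common to all 6 libraries, and none of these 36 was called different between the species by edgeR's quasi-likelihood test. That test called 81 of all 53478 contigs tested, so no call among 36 does not set abundant contigs apart. A further 3 contigs were among the 100 most abundant in all 3 P. gabriellae plants and in no P. semperflorens plant, and 4 in the reverse case.

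The P. semperflorens plants resembled each other more than the P. gabriellae plants did. Across contigs, which are not independent replicates, Pearson's r of log2 CPM was 0.90 to 0.92 between plants of P. semperflorens and 0.85 to 0.89 between plants of P. gabriellae. Between plants of different species it was 0.84 to 0.88. P. gabriellae plants 1 and 2 lay within that range, at 0.848. Plants 1 and 3 of this species, at 0.889, and plants 2 and 3, at 0.884, lay slightly above it. The common biological coefficient of variation was 0.614 in P. gabriellae and 0.531 in P. semperflorens. Neither difference was tested, and the coefficients obtained after leaving out 1 plant overlapped, at 0.530 to 0.671 and 0.481 to 0.565. The first principal component held 31.8% of the variance and separated the species. The second held 26.9%, and on it the Rivière Blanche plant had the lowest score within each species.

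**Figure D1:**
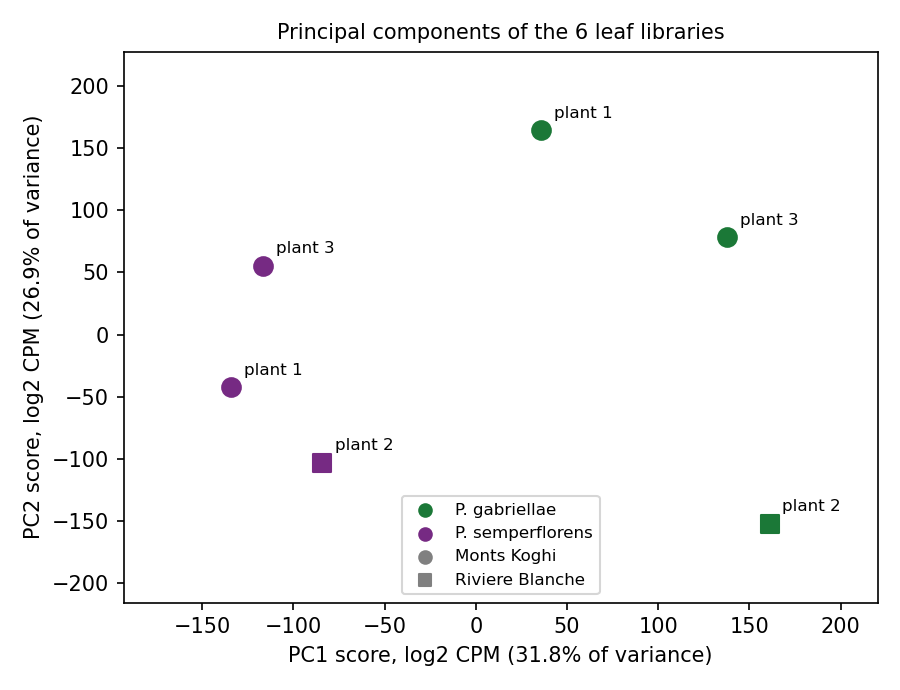
Scores of the 6 libraries on the first (x axis, 31.8% of variance) and second (y axis, 26.9%) principal components of log2 CPM, in arbitrary score units. Colour marks the species and shape the site, and the species lie on opposite sides of 0 on the first component.

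The comparison of the species asked which transcripts differ in abundance between leaves of the hyperaccumulator and of the non-accumulator. Of 53478 contigs tested, 72 were higher and 9 were lower in P. gabriellae (edgeR quasi-likelihood test, adjusted p under 0.05). With collection day as a block, and without any 1 of the 6 libraries, the same test called 0, whereas DESeq2 with this block called 2389. No run of DESeq2 with this block was made on simulated counts. The contigs called higher by the quasi-likelihood test were mostly of low abundance: 15 of the 72 had a mean of at least 10 CPM, against 8 of the 9 called lower. Of all 2003 tested contigs whose groups did not overlap and differed by at least 4-fold, 220 had such a mean, so low abundance does not set the called contigs apart. Every called contig differed by more than 4-fold. Smaller differences were mostly out of reach of the test, which recovered 1 of 100 4-fold changes on simulated counts. Of 2143 contigs called by DESeq2, 1456 differed by at least 4-fold. The 9 lower contigs had log2 fold changes of 2.35 to 4.22 in favour of P. semperflorens, and each of them held at least 10 reads in all 6 libraries. Of the 72 higher contigs, 26 held at least 10 reads in every library, with a median log2 fold change of 3.80 and a range of 2.40 to 6.30. Another 12 of the 72 had no read in any P. semperflorens library. The median over all 72 was 5.44, and it was the same with these 12 set at the bound given by 3 reads over the P. semperflorens group. A median does not move while such values stay on the same side of it, so this is no test of the sizes themselves. In all, 23 of the 72 held at most 3 P. semperflorens reads in total, and only the 12 were set at the bound. The called contigs together were a small part of the leaf RNA. The 72 took 0.123% to 0.155% of the reads in P. gabriellae and 0.00886% to 0.0114% in P. semperflorens. The 9 took 0.00697% to 0.00794% and 0.0470% to 0.0515%, respectively.

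**Figure D2:**
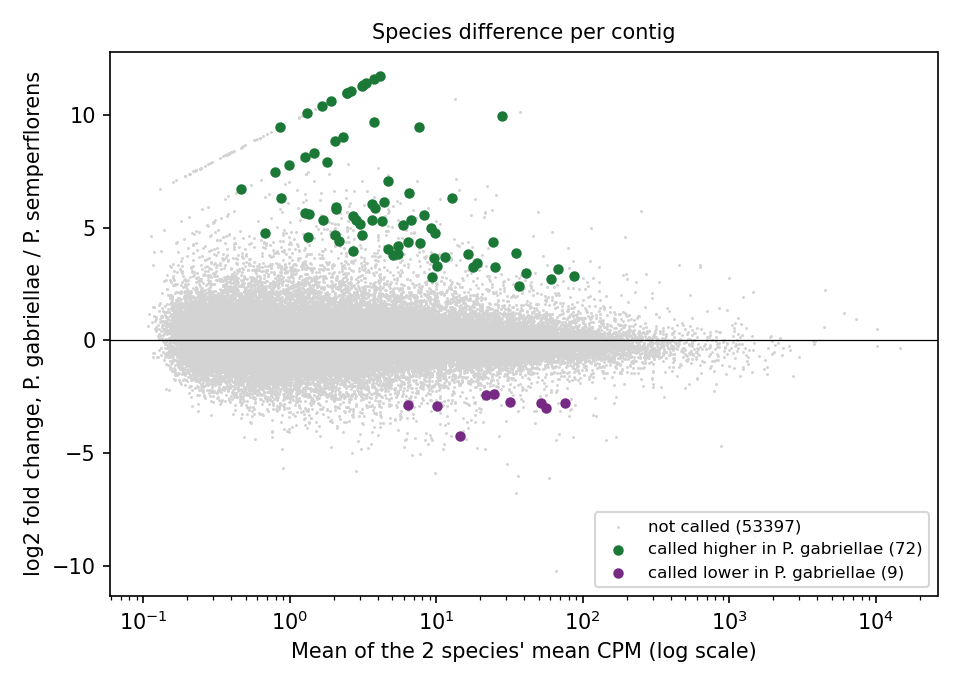
Log2 fold change between P. gabriellae and P. semperflorens (y axis) against the mean CPM of the species (x axis, log scale) for each of the 53478 contigs tested. Green marks the 72 contigs called higher in P. gabriellae and purple the 9 called lower, and the straight rows of points at the upper left are contigs with no or very few reads in P. semperflorens, whose fitted fold depends on the prior count.

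Among contigs with a mean of at least 10 CPM, the rule named 4. Pgab_v2_contig_8903 was at 56.2 ± 40.7 CPM (SD, n = 3) in P. gabriellae and at 0.0567 ± 0.0591 CPM (SD, n = 3) in P. semperflorens, where the 3 libraries held 5, 0 and 3 reads. Its log2 fold change was 9.96 with a standard error of 1.09 (edgeR adjusted p = 0.0391, and 0.173 with collection day as a block), and with 1 library left out it lay between 9.19 and 10.9. The ratio of pooled reads, 8519 against 8, each over the unscaled total of its species, was 1140, with an exact 95% interval of 576 to 2630 that covers counting error only. Pgab_v2_contig_16886 was at 25.3 ± 7.48 CPM (SD, n = 3) in P. gabriellae and at 0.317 ± 0.0530 CPM (SD, n = 3) in P. semperflorens, a log2 fold change of 6.30 with a standard error of 0.411 (edgeR adjusted p = 0.0354, and 0.173 with collection day as a block).

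In the other direction, Pgab_v2_contig_43309 was at 1.48 ± 0.403 CPM (SD, n = 3) in P. gabriellae and at 27.5 ± 13.6 CPM (SD, n = 3) in P. semperflorens. Its log2 fold change was -4.22 with a standard error of 0.50 (edgeR adjusted p = 0.0467, and 0.191 with collection day as a block). Pgab_v2_contig_15876 was at 12.3 ± 2.10 CPM (SD, n = 3) in P. gabriellae and at 99.4 ± 17.4 CPM (SD, n = 3) in P. semperflorens, a log2 fold change of -3.01 with a standard error of 0.285 (edgeR adjusted p = 0.0354, and 0.173 with collection day as a block). With this block edgeR called none of these 4 contigs. Their log2 fold changes stayed close, at 9.995, 6.26, -4.12 and -3.01 in the order above, and DESeq2 with the same block called all 4. DESeq2 with this block was not run on simulated counts, where DESeq2 without a block made 206 false calls.

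**Figure D3:**
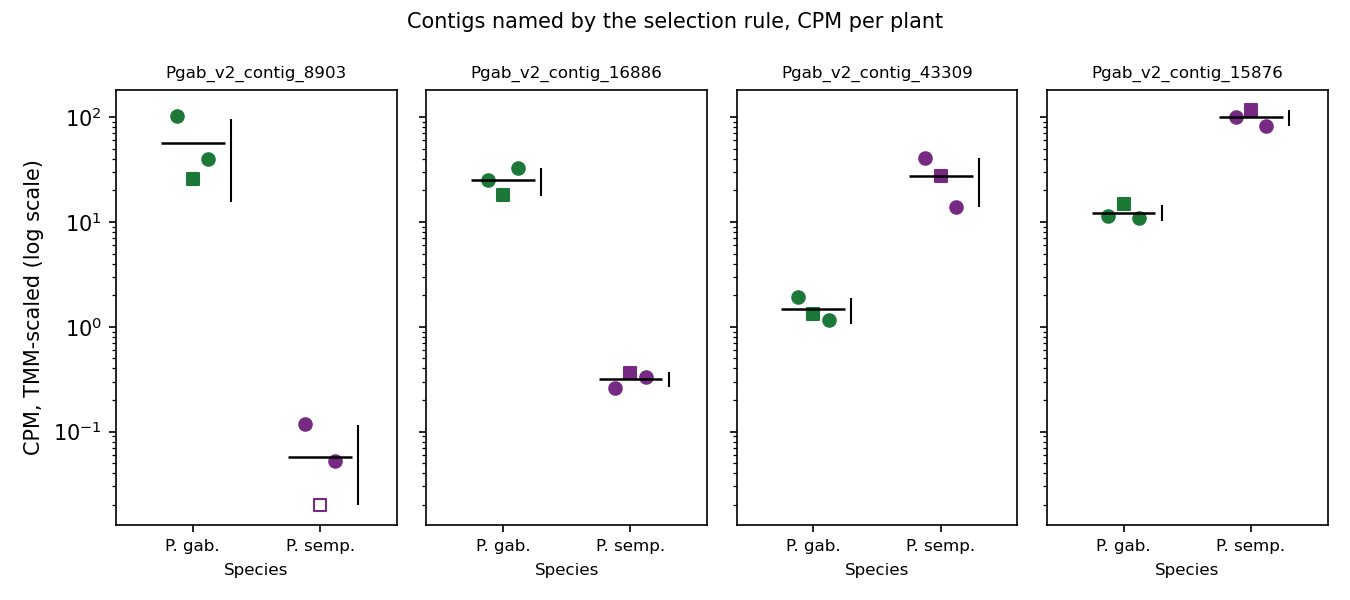
CPM scaled by TMM (y axis, log scale) in each plant for the 4 named contigs, by species (x axis). Circles are plants from Monts Koghi and squares plants from Rivière Blanche, horizontal bars are means, vertical bars span 1 SD to each side (n = 3) and end at the lowest plotted level where they would cross it, and the open square is a library with 0 reads.

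The groups of 3 plants did not overlap in any of the 81 called contigs. The pairs of plants collected on the same day, at Monts Koghi and at Rivière Blanche, therefore agree in direction by necessity, which is no separate evidence from the days or sites. The calls were close to the threshold, with adjusted p-values between 0.0354 and 0.0498 by edgeR. With collection day as a block, which leaves 2 residual degrees of freedom, edgeR called 0 contigs (5752 at an unadjusted p under 0.05). Without any 1 of the 6 libraries, or within Monts Koghi alone (2 plants per species, 6808 contigs at an unadjusted p under 0.05), edgeR also called 0, and Rivière Blanche holds too few plants for a test. DESeq2 called 2143 contigs, 1208 higher and 935 lower in P. gabriellae, among them all 81.

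Beyond the called contigs, the species were set apart by more contigs than other groupings of the plants. The 3 values of each species did not overlap in 10651 contigs, 19.9% of those tested, where chance gives 10%. The other 9 splits of the 6 libraries into 3 and 3 gave 5.29% to 15%. Of the 10651, 5614 were higher and 5037 lower in P. gabriellae. Among the 2003 of them with a fitted difference of at least 4-fold, 1261 were higher and 742 lower, or 63% higher. Among the 220 of these with a mean of at least 10 CPM, 109 were higher and 111 lower. The share of 63% depended on P. gabriellae plant 1. For non-overlapping contigs at least 4-fold apart on a scale of log2(CPM + 0.5), 62.3% were higher with all libraries. Without plant 1 the share was 49.1%, and without any other library 56.4% to 64.3%.

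Detection in 1 species was counted in both directions. In all, 69 contigs had at least 10 reads in each P. gabriellae plant and 0 reads in each P. semperflorens plant, and 0 contigs showed the reverse. The reverse count was limited to at most 2 from the start, since P. gabriellae plant 1 had 0 reads in only 2 contigs. The 69 were scarce, with a median of 1.21 CPM and a range of 0.271 to 8.58 CPM in P. gabriellae. A count of 0 allows 3 reads over the 157794786 reads of the P. semperflorens group, or 0.0190 CPM. Against this bound the CPM of the median contig was at least 62.6-fold higher in P. gabriellae. The bound covers counting error only. Sequence differences can lower P. semperflorens counts as well, so 62.6-fold is no lower bound on a difference in expression. Without P. gabriellae plant 1, 74 contigs were detected only in P. gabriellae and 61 only in P. semperflorens. Without any other single library, the numbers were 110 to 136 and 0.

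The comparison of the sites asked whether the plants of Rivière Blanche, collected in March, differed from those of Monts Koghi, collected in the preceding October and November. Site and season cannot be told apart in this design. The plants of Rivière Blanche lay both above or both below all 4 plants of Monts Koghi in 9117 contigs, 17.0% of those tested, where chance gives 13.3%. Of the 9117, 4222 were higher and 4895 lower at Rivière Blanche. Among the 1824 of them at least 4-fold apart by edgeR's fold, 342 were higher and 1482 lower. With a constant added to CPM, as for the species above, 128 were higher and 339 lower by at least 4-fold. The 8 other pairs made of 1 plant of each species were apart from the rest in 7.16% to 12.6% of contigs. On the scale with the constant, every pair without P. gabriellae plant 1 had more contigs lower than higher. Every pair with plant 1 had more higher. The excess of lower contigs is thus not particular to the sites, and a part of plant 1, from Monts Koghi, in it was not tested. With species in the model, edgeR's quasi-likelihood test called 0 contigs between the sites, with 4886 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 1200, of which 384 were higher and 816 lower at Rivière Blanche.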

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

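All alternatives were chosen before the data were examined except the robust estimation, the collection-day block in DESeq2, the comparison within Monts Koghi and limma-voom for the sites. All 81 species calls that were tested again kept their direction under every alternative, while the number called moved. RLE, upper-quartile and library-size scaling, robust estimation, limma-voom and a filter at 1 CPM in 3 libraries called 63 to 102. No low-count filter left 44 and at least 10 reads in each library left 35, of which 33 were among the 81. DESeq2 called 2143 (1456 by at least 4-fold), DESeq2 with the collection-day block 2389 (1820) and the likelihood ratio test 1457 (1267), and of the tests run on simulated counts DESeq2 without a block and the likelihood ratio test made the most false calls. The share called higher was 88.9% by the quasi-likelihood test, 56.4% by DESeq2 and 63.1% by the likelihood ratio test. With the replicate block, the collection-day block or site as a covariate, within Monts Koghi, and at an adjusted p of 0.01, edgeR called 0 contigs, and leaving out each library gave 0 to 0. The named contigs kept their direction, likewise by necessity. The log2 fold change of Pgab_v2_contig_8903 was 9.19 to 10.9 with 1 library left out (9.96 with all). The named contigs lost their calls with these blocks and with each library left out (edgeR adjusted p 0.0501 to 0.207). The replicate numbers as a set do not pair the plants, since only the plants numbered 2 shared a day: deviations of the plants numbered 1, 2 and 3 correlated at -0.002, 0.17 and 0.10, so that 0.17 is also the value for March 10, and P. gabriellae plant 1 correlated best with P. semperflorens plant 3, at 0.16. With the collection-day block, and so fewer residual degrees of freedom, the simulated comparison recovered 25 of 100 16-fold changes against 64 without it. The changed contigs were not scarce, so this cannot decide on the fall to 0 calls, and no other cause was tested.

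For the sites, DESeq2 called 1200 contigs and the other 7 alternatives 0; the cause was not tested. Contigs detected in P. gabriellae only numbered 105 at 5 reads against 0, 140 at 10 reads against at most 2, and 74 to 136 with 1 library left out. Those in P. semperflorens only numbered 0 under both thresholds and 0 to 61 with 1 library left out, the 61 without P. gabriellae plant 1, whose 2 contigs at 0 limit this count to 2 wherever it is included and 0 reads are required. With at least 10 reads in each library the coefficient of variation fell to 0.512 in P. gabriellae and to 0.429 in P. semperflorens. With the main filter and 1 plant left out it was 0.530 to 0.671 and 0.481 to 0.565. The 18 gene lists could not be tested because the files give no gene names. Depth was lowest in P. gabriellae plant 3, where 10 reads equal 0.334 CPM on the unscaled total.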

Other observations

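The tests without plant 1, of mismatched reads, of the assembled plant, of reads passed between libraries, of whether plant 1's reads alone raised the called contigs and of other splits were chosen, or replaced a test set beforehand, after results were seen; the tests of sequencing depth and of an outside source of RNA were set beforehand. The 3 tests that were replaced are given below with their values.

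P. semperflorens plant 3 held 18 contigs at least 10 times above every other library, and these took 3.71% of its reads. The 19 to 26 contigs set apart in this way in each of the other libraries except P. gabriellae plant 1 took 0.0529% to 0.153%. Its most abundant contig of all, Pgab_v2_contig_53591, held 1259351 reads there, 2.35% of the library, and it was chosen after its values were seen. The same contig held 30642 reads in P. semperflorens plant 1, 5656 in plant 2, and 116, 115 and 990 in P. gabriellae plants 1, 2 and 3. Pgab_v2_contig_15549, named for the same reason, held 620412 reads in P. semperflorens plant 3. Its CPM, relative to that plant, was 2.61% in P. semperflorens plant 1 and 0.567% in plant 2, against 2.84% and 0.414% for the first contig.

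P. gabriellae plant 1 had 2 contigs without a read, against 2062 to 3425 in the other libraries, although plant 2 was sequenced more deeply. Thinned to 29905486 reads, the total of the smallest library, plant 1 had 30 contigs at 0 and the other 5 libraries 2596 to 4380, which argues against sequencing depth. Plant 1 also held 196 contigs at least 10 times above every other library, against 18 to 26. Both values are consistent with the hypothesis that the reference was assembled from this plant, which the labels leave open.

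That hypothesis bears on the one-sidedness of the species comparison, since a transcript absent from the assembled plant has no contig. Contigs whose groups did not overlap and differed by at least 4-fold on a scale of log2(CPM + 0.5) were 62.3% higher in P. gabriellae (401 against 243). Without plant 1 the share was 49.1% (533 against 553, exact 95% interval 46.1% to 52.1%, contigs taken as independent), and without any other library 56.4% to 64.3%. This fall decides neither for missing contigs nor against a poorer match of P. semperflorens reads: the 533 higher lay within the 440 to 659 seen without other libraries, and only the 553 lower lay outside, above the 287 to 385 seen without them. In the same way the 61 contigs detected only in P. semperflorens without plant 1 show that plant 1, with 2 contigs at 0, had limited this count, and they do not show that contigs are missing. The test set beforehand for a poorer match came out as that explanation predicted: with all libraries, 63% of the contigs at least 4-fold apart by edgeR's fold were higher in P. gabriellae (60.8% to 65.1%), a share that missing contigs would give as well. It was 64.6% (62.3% to 66.8%) among contigs under a mean of 10 CPM and 49.5% (42.8% to 56.3%) among the others, where a poorer match would be expected to act too unless abundant transcripts differ less in sequence, which was not tested, so that both stay open.

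Plant 1 was the highest of the 3 P. gabriellae plants in 16 of the 72 contigs called higher. Whether its reads alone raised contigs cannot be decided from these 72, in all of which plants 2 and 3 also lay above every P. semperflorens plant, so that a contig raised by plant 1 alone was not among them. This count had been set beforehand as the test of the assembled plant, and by its stated bound it went against that hypothesis. The bound was wrong by design: an assembly from plant 1 requires only that a contig be present in plant 1, not that it be highest there. The hypothesis thus rests on the contigs at 0 and those set apart in plant 1, which were examined afterwards. Whether the 72 against 9 would even out cannot be seen, since no call remained without plant 1, and a difference between the species remains open.

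In the test of other splits, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many calls: 81, all of at least 4-fold, against a highest other count of 0. With 10 splits the share cannot fall under 0.05. For DESeq2 the real split gave 2143 and the highest other 844, which grouped P. gabriellae plants 1 and 3 with P. semperflorens plant 3, all from Monts Koghi, and left both Rivière Blanche plants in the other group.

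P. gabriellae plant 1 and P. semperflorens plant 3, collected on the same day, shared 96 contigs that were at least 10 times above each of the other 4 libraries. None of these was among the 81, by necessity, since the species overlap in such contigs and in none of the 81. The 96 took 1.42% and 0.548% of the reads of these libraries and at most 0.0251% in the others. The other pairs that include P. gabriellae plant 1 shared 12 to 71, the 71 with P. gabriellae plant 3, taken on another day. Pairs without plant 1 shared 0 to 6, among them the other same-day pairs at 0 and 1. Those same-day pairs lack plant 1 and so cannot show whether a shared day matters. Reads passed from plant 1 into the other library would carry all of plant 1's own contigs at a like ratio. The median ratio over the shared contigs was 0.525, and 35.8% of the 461 contigs abundant in plant 1 were more than 10 times below it. The shared contigs were chosen as high in the recipient too, which can raise that median and with it the share. Reads passed the other way cannot explain a median level 1.91 times higher in the recipient (95% bootstrap interval 1.52 to 2.21). That interval takes the contigs as independent and comes from this pair of libraries alone. The median does not exclude such passage for single contigs. The test set beforehand took the share of too low ratios for both directions, and at 35.8% and 17.4% (of 144 contigs abundant in P. semperflorens plant 3) it left the second direction undecided, so the ratio of 1.91 was used there afterwards. One outside source of RNA on both plants, such as another organism, could not be decided: the SD of the log2 ratio was 1.23 over the shared contigs (0.976 to 1.48) and 1.36 over other contigs of like abundance. A response of both plants to the conditions of that day also remains open and untested, and without sequences the contigs cannot be assigned to either.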
